A study of Mus musculus with 6 samples.

How the data were processed

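Messenger RNA was profiled in 6 libraries of primary mouse microglia, 3 from Nus1fl/fl mice (Ctrl) and 3 from Nus1 conditional knockout mice (cKO). Per the labels' protocols, mice received tamoxifen, a drug used to switch on inducible Cre recombinases, by intraperitoneal injection at 100 mg/kg on 5 days from postnatal day 28. Brains were taken 30 days after the last injection and microglia were isolated by flow cytometry. The labels also describe culture of primary microglia in medium with serum, and do not say whether the sequenced cells were cultured. The Cre driver and the sex of the mice are not given in the sources used here. RNA was extracted with TRIzol and libraries were made with an mRNA kit. Samples were grouped by the genotype in their titles.

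Per the submitters' processing notes, Bowtie2 2.4.5, DESeq2 1.34.0 and the genome build mm39 were used; the read counter is not given in the sources used here. The deposited table gives, for each gene and library, an estimated (expected) read count, FPKM, TPM and a normalized count, and for each gene the authors' log2 fold change, p-value and q-value, per the file headers. The deposited expected counts are not normalized, and 11.1% of the entries are not whole numbers (tolerance 1e-06). The deposited FPKM values are reads scaled by gene length and library size, and the deposited TPM values are length-scaled shares with a fixed total over all genes the authors quantified, of which the rows used here hold 59.4% to 60.3%. The deposited normalized counts, a signal scaled between libraries, equalled the count rounded up and divided by 1 size factor per library in 100% of the entries. The authors' size factors ranged from 0.987 to 1.02. The authors' log2 values are ratios of cKO over Ctrl. Another 8 columns with the authors' averages were not used, and 0 columns of values of other samples were present.

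The table holds 4656 rows, all of type mRNA, and all have an authors' q-value under 0.05. In 100% of the 4652 rows with a p-value above 0, the q-value equalled a Benjamini-Hochberg adjustment of the p-value over 15835 genes, within a relative tolerance of 1e-06. The rows are then the authors' complete list of called genes, 29.4% of those tested, with 2168 higher and 2488 lower in cKO by the authors' deposited table. The design fixed before the data were examined had assumed whole counts of all genes. Expected counts were therefore rounded to whole numbers, and adjusted p-values were computed over 15835 genes, taking the genes without a row to have larger p-values than those with one. Normalization and estimates of spread rest on the deposited rows, which were selected on the comparison itself, so that TMM factors could differ from those of a full table, and dispersions are those of called genes. A gene list was matched by exact symbol, and a member without a row counted as unknown.

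The main test was edgeR's quasi-likelihood F-test (edgeR 4.0.16, R 4.3.3) with TMM normalization and filterByExpr, which left 4640 genes and removed 16. The threshold was an adjusted p of 0.05, and genes with an absolute log2 fold change of at least 1 were also counted. Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), with Benjamini-Hochberg adjustment over the lists. The 35 lists were fixed before the data were examined; 24 had at least 4 tested members and 11 had fewer. Alternatives were RLE, upper-quartile and library-size scaling, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, limma-trend on log2(FPKM + 1), a replicate block, robust dispersion, each replicate left out in turn, an estimated correlation per list, prior count 0.5 and fry. Alternatives chosen after seeing the data were the authors' size factors, adjustment over the deposited rows alone, counts rounded up, a Fisher exact test of direction and a hypergeometric test of the share of list members with a row. Single genes were also tested with an exact permutation test. Python 3.11.15 with SciPy 1.17.1, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9 was used for the remaining steps.

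Genes were named by a rule fixed before the data were examined. It takes Nus1, Dhdds, Lcn2 and Slc22a17; the 10 highest and 10 lowest log2 fold changes past the threshold, with a mean of at least 5 CPM, no overlap between the groups and no predicted gene model; and of each list up to 4 members past the threshold with the smallest p. Other genes named here, such as those in the pathway paragraph of the closing section, were chosen after their values were seen. A few genes that the rule takes are not reported here. TPM values are given as mean ± SD over 3 libraries and log2 fold changes with SE.

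Depth could be judged only from the deposited rows, whose reads summed to between 10786150 and 11033144 per library; the 10 most abundant genes took 7.15% to 7.24% of them. Libraries of a group were compared before averaging. The median chi-square between a pair of them was 1.26 to 1.74 times its value for sampling noise alone, so no pair was merged as 1 sequencing library counted repeatedly; this does not show that the libraries come from separate animals or cultures. The common biological coefficient of variation was 1.64%. On a principal component analysis of the tested rows the first component held 91.7% of the variance and separated the genotypes. These rows had been selected for a difference between the genotypes, so this separation is not independent evidence of one. The test was checked on simulated counts of 4640 genes for cKO against Ctrl, with 50 genes changed at each size: 76% were recovered at a log2 fold change of 0.25, 94% at 0.5, 100% at 1 and 98% at 2, and 4.17% of the calls were false. Most simulated genes were unchanged, signs were balanced and adjustment was over the 4640 genes alone. The real rows were nearly all called and were adjusted over 15835 genes, so these rates do not carry over to them. Among simulated lists, camera called 1 of 1 shifted list and 0 of 19 random lists. Gene coordinates are those of the deposited table, on mm39 and counted from 1; the reference annotation on another build was not used here.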

Results

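RNA sequencing measured messenger RNA in primary microglia, the resident macrophages of the brain, from adult mice. The 6 libraries fall into 2 groups of 3: Nus1fl/fl control mice, in which the gene carries sites for Cre recombination but is intact (Ctrl), and Nus1 conditional knockout mice (cKO). Nus1 encodes a subunit of cis-prenyltransferase, the enzyme that makes the lipid chain of dolichol, on which the sugar tree for protein N-glycosylation is built. The series title links loss of NUS1 in microglia to the secreted iron-siderophore carrier lipocalin 2 (Lcn2), its receptor Slc22a17 and iron transport, so the comparison asks how the transcriptome of microglia differs between the genotypes. Whether the Ctrl mice carried a Cre is not given in the sources used here. If only the cKO mice did, an effect of Cre could not be told apart from that of losing Nus1. Reads in the deposited rows came to between 11002519 and 11033144 in the Ctrl libraries and to between 10786150 and 10983767 in the cKO libraries. These sums are part of each library and not its depth, because the deposited table holds 4656 genes, each with a q-value under 0.05 in the authors' own comparison. A gene without a row was either not called in that comparison or not tested in it, and its level and change are unknown here. Every count of changed genes below starts from genes that the authors had already called on these libraries.

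The targeted gene was lower in every library labelled cKO. Nus1 (ENSMUSG00000023068, chromosome 10, 52293643 to 52316288, plus strand, mm39) had 59.8 ± 0.902 TPM in Ctrl (SD, n = 3) and 13.9 ± 0.252 TPM in cKO (SD, n = 3). The edgeR fold on TMM-scaled counts was 0.234. Counts scaled to the reads in the deposited rows (CPM) were 260, 269 and 258 in the Ctrl libraries and 62.9, 59.6 and 61.7 in the cKO libraries. The log2 fold change was -2.10 ± 0.04 (SE; edgeR quasi-likelihood test, adjusted p = 1.2e-33), beside -2.14 in the authors' deposited table. An exact two-sided permutation test of 3 against 3 libraries gave p = 0.1, the smallest value this design allows. Which exons were deleted is not given in the sources used here, and reads of remaining exons count towards the gene. Dhdds, the other subunit of the enzyme, was not among the deposited rows.

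**Figure D1:**
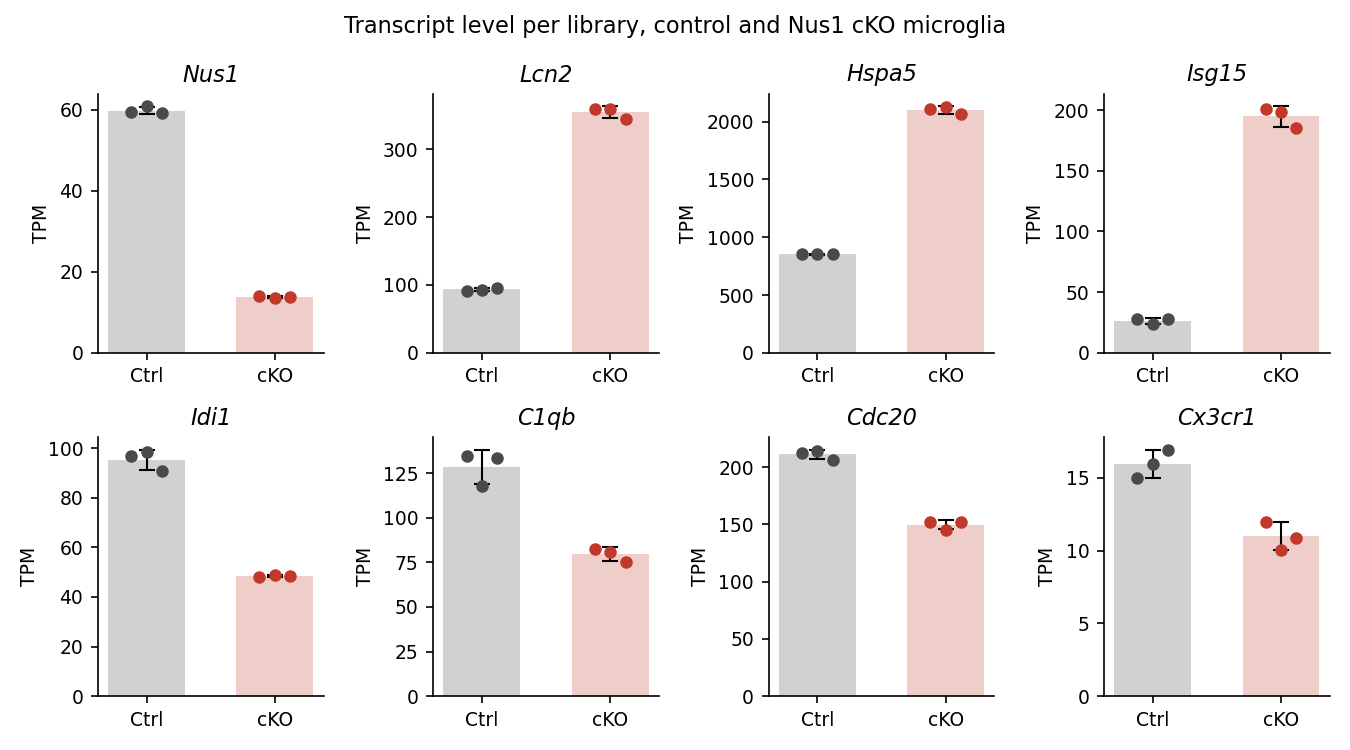
Transcript level of 8 genes in each library, in deposited TPM (a length-scaled share of all transcripts, vertical axes, each starting at 0), for control (Ctrl, grey) and Nus1 knockout (cKO, red) microglia. Points are the 3 libraries of a group, bars the mean and error bars the SD; Nus1, Idi1, C1qb, Cdc20 and Cx3cr1 lie lower in every cKO library, and Lcn2, Hspa5 and Isg15 higher, with Isg15 at 26.5 TPM in Ctrl and 195 TPM in cKO.

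Lcn2, the carrier named in the series title, rose from 93.6 ± 2.31 TPM in Ctrl to 354 ± 8.49 TPM in cKO (SD, n = 3 each), and the edgeR fold on TMM-scaled counts was 3.81. Its log2 fold change was 1.93 ± 0.04 (SE, adjusted p = 6.6e-31), beside 1.89 in the authors' deposited table, and the exact two-sided permutation p was again 0.1, the smallest possible. Lcn2 (ENSMUSG00000026822) lies on chromosome 2 from 32274649 to 32277751 on the minus strand. Its receptor Slc22a17 was not among the deposited rows. Of 38 genes fixed as iron handling, 12 were among the tested rows, of which 6 rose and 6 fell, and the list did not pass the set test (camera, adjusted p = 0.883). The transferrin receptor Tfrc fell by 0.29 on the log2 scale, the iron chaperone Pcbp1 by 0.25 and the ferritin light chain Ftl1 by 0.22, from 9867 ± 123 to 8427 ± 394 TPM. The ferroxidase ceruloplasmin (Cp), named after its value was seen, rose by 0.95 from 0.897 TPM. Lcn2 was picked by the study, so its place in this list is not independent evidence of direction. The median of the list was 0.02; it was 0.06 with RLE and 0.07 with upper-quartile scaling, where 6 rose and 4 fell, and turned to -0.02 with the authors' size factors.

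Across the deposited rows 4640 genes were tested, of which 2154 were higher and 2339 lower in cKO at an adjusted p under 0.05, so that 47.9% of the calls were higher. With DESeq2, whose size factors here came from the deposited rows alone, the split was 2168 higher and 1510 lower, or 58.9% higher. The authors' own calls were 2168 higher and 2488 lower. Their size factors in edgeR gave 2154 higher and 2486 lower, or 46.4% higher. Changes upwards were larger than changes downwards. An absolute log2 fold change of at least 1 was reached by 207 of the higher genes (9.61%) and by 22 of the lower genes (0.941%), and the median log2 fold change was 0.37 among the higher and -0.21 among the lower calls. The labels call the replicates biological but do not tie each library to an animal, so p-values measure the spread between these samples.

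Among genes with a mean of at least 5 CPM, the largest increases were those of Apol9a (log2 fold change 4.25 ± 0.19, SE) and Apol9b (3.80 ± 0.22), near-identical apolipoprotein L genes between which reads could be split wrongly, so their separate values are uncertain. Next came Chac1 (3.30 ± 0.23), which degrades glutathione, and Ly6a (3.10 ± 0.15), which encodes the surface antigen Sca-1. Isg15, a ubiquitin-like modifier induced by interferon, rose by 2.88 ± 0.07, and the interferon-induced exonuclease Isg20 by 2.70 ± 0.12. Soat2, which esterifies cholesterol, rose by 2.75 ± 0.10 from 3.17 to 21.1 TPM. Angptl6 rose by 2.72 ± 0.15, the pseudokinase Trib3 by 2.60 ± 0.05 and the aquaglyceroporin Aqp9 by 2.12 ± 0.08. Adjusted p-values of these 10 genes ranged down from that of Chac1 at 4.6e-15.

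Among genes with the same minimum of 5 CPM, the largest decreases below Nus1 were those of the macrophage metalloelastase Mmp12 (log2 fold change -1.21 ± 0.11, SE) and the mannose receptor Mrc1 (-1.14 ± 0.08). Genes of the Ms4a membrane protein cluster followed closely, of which Ms4a6b fell by 1.07, Ms4a4a by 1.03 and Ms4a7 by 0.91. Reads can be shared within this family, so these values carry that uncertainty. Gas6, a bridging ligand between dying cells and receptors of the TAM family, fell by 0.98 ± 0.08. Idi1, the isopentenyl diphosphate isomerase of the mevalonate pathway, fell by 0.96 ± 0.03, from 95.4 to 48.5 TPM. The creatine-synthesis enzyme Gatm fell by 0.96 ± 0.13 and the heparanase Hpse by 0.93 ± 0.16. The highest adjusted p of the 10 lower genes was that of Ms4a4a, at 2.6e-05.

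**Figure D2:**
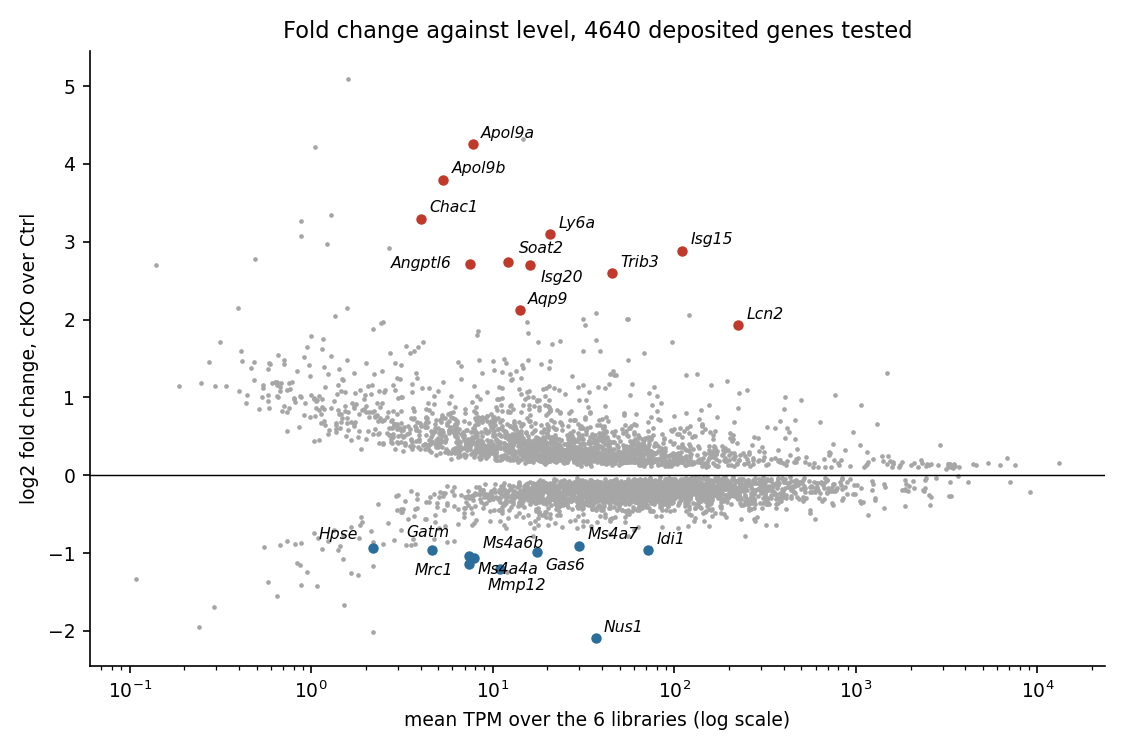
Log2 fold change of cKO over Ctrl (vertical axis) against mean TPM over the 6 libraries (horizontal axis, log scale) for the 4640 deposited genes tested, 1 grey point per gene. Red and blue points are the genes with the largest increases and decreases under the naming rule, with Lcn2; the gap around 0 reflects that the table holds genes called by the authors.

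Endoplasmic reticulum chaperones and other genes of the unfolded protein response rose together. Of 33 genes fixed for this response, 31 were tested, and all 31 rose, with a median log2 fold change of 0.86 (camera, adjusted p = 5.5e-16; adjusted p = 0.055 with an estimated correlation). The chaperone BiP (Hspa5) rose by 1.31 ± 0.02 (SE), from 854 ± 3.10 to 2101 ± 31.7 TPM (SD, n = 3 each). Hsp90b1, the chaperone GRP94, rose by 0.90, the disulfide isomerase Pdia6 by 0.97 and Herpud1, a component of the degradation machinery of the reticulum, by 1.72. Among 42 genes of dolichol synthesis and N-glycosylation, 22 were tested; 11 rose and 11 fell (adjusted p = 0.765). The oligosaccharyltransferase subunits Rpn1 (0.35), Stt3a (0.34) and Magt1 (0.39) rose, as did the mannosyltransferase Alg12 (1.12), named after its value was seen. Further subunits, also named after their values were seen, went both ways. Ddost (0.25), Rpn2 (0.18), Krtcap2 (0.26) and Ostc (0.33) rose, and Ost4 (-0.42), Dad1 (-0.25) and Stt3b (-0.09) fell. For this list the mean, -0.02 with Nus1 included, and the median, 0.02, differed in sign; the median was 0.06 with RLE and 0.07 with upper-quartile scaling and turned to -0.02 with the authors' size factors.

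Transcripts of cholesterol and isoprenoid synthesis were lower in cKO. Of 26 listed genes 21 were tested, and all 21 fell, with a median log2 fold change of -0.43 (camera, adjusted p = 1.0e-06; adjusted p = 0.055 with an estimated correlation). Besides Idi1, the sterol oxidase Msmo1 fell by 0.51 and the farnesyl diphosphate synthase Fdps by 0.43, from 317 to 234 TPM. Of 16 genes of cholesterol efflux and lysosomal export, 8 were tested; 5 rose and 3 fell (adjusted p = 0.546). The lysosomal cholesterol transporters Npc1 and Npc2 each rose by 0.49, Soat1, a paralog of Soat2, rose by 0.18, and the desaturase Scd2 fell by 0.42.

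Genes induced by interferon had a median log2 fold change of 1.17, the largest among the 24 lists with at least 4 tested members. Of 48 interferon-stimulated genes 38 were tested; 35 rose and 3 fell (camera, adjusted p = 6.0e-14; adjusted p = 0.404 with an estimated correlation). The antiviral enzymes Rsad2 and Oas3 rose by 2.08 ± 0.05 and 1.60 ± 0.04 (SE), and the ubiquitin ligase Rnf213 by 1.29 ± 0.03. The 3 that fell, named after their values were seen, were Ifi206 (-0.91), Zbp1 (-0.88) and Slfn5 (-0.40). Ifi206 was at -0.60 without cKO replicate 3. The call of Zbp1 ended without Ctrl replicate 1 (adjusted p = 0.067), Ctrl replicate 3 (adjusted p = 0.0593) or cKO replicate 3 (adjusted p = 0.0776), and on the log2(FPKM + 1) scale (adjusted p = 0.171).

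Antigen presentation and inflammatory genes also rose. Of 25 genes of antigen presentation 18 were tested; 17 rose and 1 fell, with a median of 0.56 (adjusted p = 5.5e-06; adjusted p = 0.253 with an estimated correlation). The class I genes H2-T23 and H2-K1 rose by 1.30 and 0.61, the peptide transporter Tap1 by 1.16 and beta-2-microglobulin (B2m) by 0.39, from 2533 to 3298 TPM. The member that fell, Ifi30 at -0.09, was named after its value was seen, and its call ended with upper-quartile scaling (log2 fold change -0.04, adjusted p = 0.299), with RLE size factors (-0.06, adjusted p = 0.114), with DESeq2 (-0.06, adjusted p = 0.297) and on the log2(FPKM + 1) scale (-0.10, adjusted p = 0.137). Of 43 inflammatory and NF-kB genes 25 were tested; 20 rose and 5 fell, with a median of 0.64 (adjusted p = 0.00094; adjusted p = 0.124 with an estimated correlation). The chemokines Cxcl10 and Ccl7 rose by 1.93 and 1.09, and Tnfaip2, induced by tumour necrosis factor, by 0.64. Lcn2 belongs to this list too. The receptors Tlr2 and Cd14, named after their values were seen, fell by 0.52 and 0.44.

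**Figure D3:**
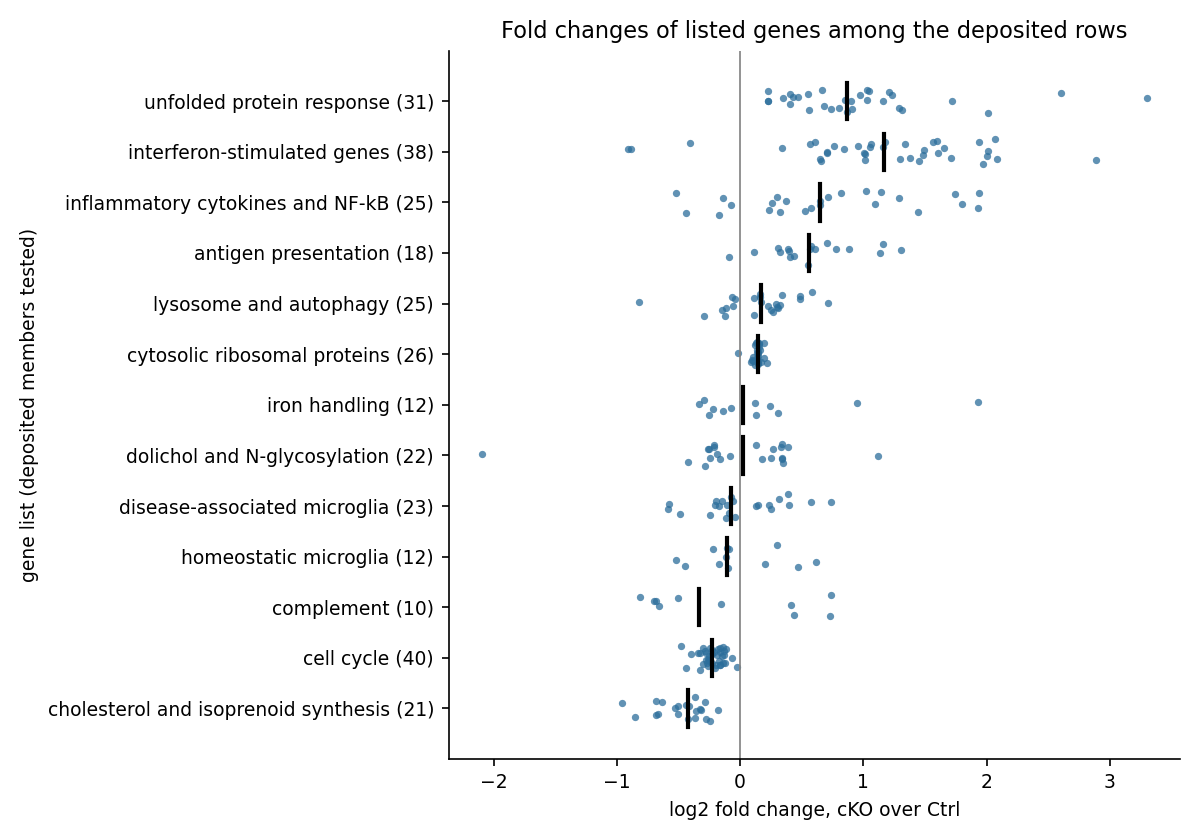
Log2 fold change of cKO over Ctrl (horizontal axis) of the tested members of 13 gene lists (vertical axis, number of members in parentheses), 1 point per gene with vertical jitter, and the median as a black bar. The points of the unfolded protein response lie right of 0 and those of cholesterol synthesis left of it; the iron handling and N-glycosylation lists have members on both sides, with medians of 0.02.

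Markers of microglial states changed in both directions. Of 30 homeostatic microglia genes 12 were tested; 4 rose and 8 fell (adjusted p = 0.765), and with RLE or upper-quartile scaling 4 rose and 4 fell. The fractalkine receptor Cx3cr1 fell by 0.52 from 15.98 TPM in Ctrl, a fold of 0.695 on TMM-scaled counts, while Gpr84 rose by 0.61 and Golm1 by 0.30. The 12 tested homeostatic genes had a median level of 35.5 TPM in Ctrl, beside 121 TPM for the 40 tested cell-cycle genes. No sorted or cultured reference microglia were compared, so these levels do not decide whether the cells were cultured. The baseline state of the Ctrl cells is therefore not known. Of 34 genes of disease-associated microglia 23 were tested; 9 rose and 13 fell (adjusted p = 0.822), and 9 rose and 7 fell with RLE or upper-quartile scaling. Its mean was 0.00 and its median -0.08, which was -0.04 with RLE, -0.03 with upper-quartile scaling and -0.12 with the authors' size factors. The lipase Lpl fell by 0.49 and the growth factor Igf1 by 0.58, and Cd74, the invariant chain of class II molecules, rose by 0.57.

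Complement and phagocytosis genes also went both ways. Of 23 complement genes 10 were tested; 4 rose and 6 fell (adjusted p = 0.872). The chains of C1q fell, C1qb by 0.68 and C1qc by 0.66, and C1qa, named after its value was seen, by 0.70. The complement receptor subunit Itgam rose by 0.73 and C3 by 0.43. Of 32 phagocytosis receptor genes 18 were tested; 7 rose and 10 fell (adjusted p = 0.765). Besides the decreases of Mrc1 and Gas6, the Fc receptors Fcgr2b and Fcgr1 rose by 0.61 and 0.46. Of 51 lysosome and autophagy genes 25 were tested; 17 rose and 7 fell, with a median of 0.17 (adjusted p = 0.0211; adjusted p = 0.404 with an estimated correlation). The call of this list ended with a Fisher exact test of direction (adjusted p = 0.113), and with RLE or upper-quartile scaling 17 rose and 4 fell. The autophagy receptor Sqstm1 rose by 0.71, the protease Lgmn by 0.32 and progranulin (Grn) by 0.30.

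Cell-cycle transcripts were lower in cKO by a small amount. Of 42 genes 40 were tested; 39 fell and 1, the tubulin gene Tubb5, had a log2 fold change of -0.03 and did not pass. The median was -0.23 (camera, adjusted p = 2.4e-08; adjusted p = 0.179 with an estimated correlation). With upper-quartile scaling 35 fell and 0 rose, and 1 of the 40 members had a value above 0. The anaphase activator Cdc20 fell by 0.48, from 211 ± 4.10 to 150 ± 4.06 TPM (SD, n = 3 each), the helicase Hells by 0.40 and the ribonucleotide reductase subunits Rrm2 and Rrm1 by 0.44 and 0.30. Of 59 cytosolic ribosomal protein genes 26 were tested; 25 rose, with a median of 0.14 (adjusted p = 7.3e-05; adjusted p = 0.253 with an estimated correlation). Rpl12, Rpl9 and Rpl3 rose by 0.22, 0.19 and 0.15. The remaining member, Rpl8, was at -0.02 and turned to a value above 0 with RLE or upper-quartile scaling. Many ribosomal protein genes have processed pseudogenes that can share their reads.

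Of 66 oxidative phosphorylation genes 16 were tested; 3 rose and 10 fell (adjusted p = 0.209), and 3 rose and 6 fell with upper-quartile scaling. Cytochrome c (Cycs) fell by 0.42 and Sdhd by 0.29, and Uqcrq rose by 0.25. Of 31 glycolysis and hypoxia genes 16 were tested; 11 rose and 5 fell (adjusted p = 0.0804), with Ndrg1 at 0.93, the oxidoreductase Ero1a at 0.75 and Vegfa at 0.73. This list passed without cKO replicate 2 (adjusted p = 0.0268). Of 31 antioxidant and ferroptosis genes 19 were tested; 8 rose and 9 fell (adjusted p = 0.822), with a mean of 0.18 and a median of -0.06, which was -0.02 with RLE, -0.01 with upper-quartile scaling and -0.10 with the authors' size factors. The chains of the cystine-glutamate exchanger rose, Slc3a2 by 0.48 and Slc7a11 by 0.42. Of 33 immediate early and dissociation genes 12 were tested; 5 rose and 7 fell (adjusted p = 0.546), with a mean of 0.13 and a median of -0.13, or -0.08 with upper-quartile scaling. Fos rose by 0.48, and the chaperone Hsph1 and the NF-kB regulator Nfkbid fell by 0.44 and 0.61. Of 25 TGF-beta signalling genes 4 were tested; 3 rose and 1 fell (adjusted p = 0.765), with Id3 at -0.53.

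Genes marking other cells that a microglial fraction could hold had few rows. Of 20 markers of border-associated macrophages 9 were tested; 3 rose and 6 fell (adjusted p = 0.546). Siglec1, which interferon also induces, rose by 0.96, and Cd36 fell by 0.46, beside the decreases of Mrc1 and Ms4a7. Of 20 monocyte markers 7 were tested; 3 rose and 4 fell (adjusted p = 0.765), with a mean of 0.01 and a median of -0.14, or -0.09 with upper-quartile scaling. S100a4 fell by 0.28, from 2833 to 2349 TPM, Ms4a6c by 0.78 and Ms4a4c by 2.02. Astrocyte markers had 4 tested members of 25 (3 rose and 1 fell, adjusted p = 0.257, mean -0.17 and median 0.38). Clu rose by 0.49 and Cpe by 0.35. Aldh1l1 was at 0.383 TPM in Ctrl, and its decrease lost its call without cKO replicate 3 (log2 fold change -1.38, adjusted p = 0.06). Endothelial and mural markers had 4 of 30 (3 rose and 1 fell, adjusted p = 0.268). Besides Ly6a, which interferon also induces, Slc2a1 rose by 0.38 and Pecam1 by 1.38 from 0.26 TPM. Egfl7 fell by 0.33, a call that ended with DESeq2 (adjusted p = 0.0606).

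Other cell-type lists had fewer than 4 tested members and were not tested as sets. Neutrophil markers had 3 of 28, all higher: Lcn2, Mmp9 (1.24) and Csf3r (0.90). T and NK cell markers had 3 of 28, all higher, with Ccl5 at 1.74 and Cd28 at 0.43. Oligodendrocyte lineage markers had 3 of 31, of which 1 rose (Cnp, 0.26) and 2 fell (Qdpr, -0.26). B cell and plasma cell markers had 1 of 20 (Bank1, 0.60), neuron markers 1 of 30 (Syn1, 0.40), erythroid markers 1 of 15 (Tfrc, -0.29) and fibroblast and extracellular matrix genes 1 of 30. That gene, Col6a3, had 0.0367 TPM in Ctrl and 0.243 TPM in cKO, and its call ended on the log2(FPKM + 1) scale (adjusted p = 0.107). Dopaminergic neuron, choroid plexus and ependymal, mitochondrially encoded and sex-linked lists had 0 members among the deposited rows.

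The set tests compared each list with the other deposited rows, and 8 of 24 lists passed, 6 upwards and 2 downwards; 0 passed with an estimated correlation, where 18 passed with fry. Adjusted over the list alone, members past the threshold were as counted above in every list except antioxidant and ferroptosis (8 rose and 11 fell), disease-associated microglia (9 and 14), lysosome and autophagy (17 and 8) and oxidative phosphorylation (3 and 12).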

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

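The authors' size factors, adjustment over the deposited rows alone, rounding up, the Fisher test and the hypergeometric test were chosen after seeing the data. The count of genes past the threshold, 4493, lay between 3678 (DESeq2) and 4640 (authors' size factors), and between 4284 and 4405 with 1 library left out. The Nus1 log2 fold change lay between -2.11 and -2.07 with 1 library left out. With DESeq2, 1510 genes were lower in place of 2339, and on the log2(FPKM + 1) scale 96 genes reached an absolute log2 fold change of at least 1 in place of 229; that scale shrinks changes of low genes, and RLE size factors alone, which DESeq2 also uses, gave 1876 lower genes in edgeR, so scaling accounts for part of the first difference and the cause of the rest was not tested. The 8 lists past camera became 0 with an estimated correlation, a setting that replaces the preset 0.01 by a value estimated from 4 residual degrees of freedom. The size of that value did not end every call. It was -0.004 for cholesterol and isoprenoid synthesis and -0.010 for inflammatory and NF-kB genes, both below the preset. Which other part of the setting ended these calls was not tested. With fry, which asks whether a list moves and not whether it moves more than other genes, 18 lists passed, 14 upwards and 4 downwards; for the homeostatic, complement and phagocytosis lists fry pointed upwards while the median was below 0. The hypergeometric test of how many list members had a row passed 13 lists, and expression level was not matched in it. With 1 library left out 8 to 9 lists passed. With the replicate block 4464 genes passed, 2159 higher and 2305 lower, with 8 lists, and no list call changed. Same-numbered libraries did not deviate together (r across 4154 genes of 0.044, -0.0937 and -0.0692, with other pairs between -0.0524 and 0.106). These values gave no sign that the numbers pair the samples. Pairing cannot be excluded by them, because the rows had been selected on the comparison of the genotypes. Of the values of single named genes under other settings, 2459 kept their call, 11 lost it and 0 reversed. RLE, upper-quartile, library-size and authors' scaling shifted the median gene by 0.04, 0.05, 0.01 and -0.04 on the log2 scale against TMM. Depth beyond the deposited rows is unknown, so genes without a row cannot be called unchanged.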

Other observations

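The pathway annotation in the deposited table was examined after the report's lists had been seen. Of 198 pathways with at least 20 tested rows, 31 were split between higher and lower genes differently from the other annotated rows, of which 46.3% were higher (Fisher exact test, adjusted over the 198 pathways): 14 were higher more often and 17 lower more often. The test counts genes as independent, so its p-values allow neither for correlation between genes nor for the spread between libraries. In the spliceosome 81 of 82 genes were lower (median log2 fold change -0.18, adjusted p = 3.2e-19), in nucleocytoplasmic transport 74 of 77 (-0.18, adjusted p = 3.1e-15) and in ribosome biogenesis 53 of 55 (-0.25, adjusted p = 7.2e-11). With upper-quartile scaling these were 80, 71 and 52 genes. Among them the splicing factor Srsf2 fell by 0.33, the nuclear transport GTPase Ran by 0.33 and the ribonucleoprotein component Nop10 by 0.64. In DNA replication 22 of 23 genes were lower, Pcna by 0.23 and Mcm6 by 0.20, and in RNA polymerase 21 of 22, where Polr1b fell by 0.36. In oxidative phosphorylation 29 of 34 genes were lower (-0.14, adjusted p = 0.00209; 26 with upper-quartile scaling), where the shorter list in the report did not pass. The ribosome pathway, with 36 genes higher and 27 lower, did not pass (adjusted p = 0.278), where the report's list of cytosolic ribosomal proteins passed with the preset correlation and not with an estimated one (adjusted p = 0.253). That pathway also holds mitochondrial ribosomal proteins, Mrpl34 and Mrps6 among them. It is therefore a wider set, and its result does not bear on the cytosolic genes alone.

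Among pathways that were higher more often, in cell adhesion molecules, a term that includes class I genes such as H2-T23 and H2-K1, 31 of 35 genes were higher (median log2 fold change 0.43, adjusted p = 7.7e-06), with the integrin Itgb7 at 0.79, in cytokine-cytokine receptor interaction 36 of 46 (0.40, adjusted p = 0.000275) and in JAK-STAT signalling 31 of 40 (0.34, adjusted p = 0.00101), with Socs3 at 0.82. These counts were the same under all 5 scalings run. Related terms were divided. NOD-like receptor signalling (57 of 75 higher, adjusted p = 5.2e-06), TNF signalling (32 of 45, adjusted p = 0.00659) and antigen processing and presentation (23 of 32, adjusted p = 0.0252) passed. Others did not pass, among them focal adhesion (34 higher and 20 lower, adjusted p = 0.099), chemokine signalling (adjusted p = 0.157) and NF-kappa B signalling (adjusted p = 0.282). The median level of the 40 listed cell-cycle genes was 121 TPM in Ctrl and 103 TPM in cKO.

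In the following paragraphs the tests of other splits, of repeated counting, of whole counts and of scaling were chosen after their results, or related values, had been seen; the others were fixed before. The real split of the 6 libraries gave 4493 genes past the threshold and the highest of the other splits gave 0; 1 of the 10 splits gave as many. With 10 splits the share cannot fall under 0.1, and the rows had been selected on the real split.

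Libraries of a group differed little, with a common biological coefficient of variation of 1.64%. One sequencing library counted several times would leave only sampling noise. The closest pair, Ctrl replicates 1 and 2, had a median chi-square 1.26 times that of sampling noise (95% bootstrap interval 1.17 to 1.36), which argues against it. Over rows with whole counts alone, a check added after that result, the closest pair was at 1.25 (1.15 to 1.36). Selection of called genes favours those with a low spread. Rows with large fold changes, which need no low spread to be called, had a coefficient 1.36 times that of rows with small ones (interval 1.23 to 1.56; 2.21% over 58 genes against 1.63% over 2711), so the selection cannot be excluded as a part of it. Cells pooled from several animals or grown in 1 culture, if they were cultured, would also give a low spread, and the labels do not decide it.

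The fall of the cell-cycle genes may have a technical source in scaling, since the changes are small. Its median lay nearest 0 with upper-quartile scaling, at -0.18 (95% bootstrap interval -0.21 to -0.13), and stayed below 0 under all 5 scalings run. The alternatives shifted the median gene by only -0.04 to 0.05 on the log2 scale against TMM. None of them could bring the TMM median of -0.23 near 0, so this test cannot decide whether scaling is the source. A p53 response to DNA damage would raise p53 targets. Of 15 targets with a row 33.3% were higher (exact 95% interval 11.8 to 61.6), and Bax and Rps27l fell by 0.44 and 0.25, which argues against a general rise of these 15 targets. Their share was not shown to differ from that of the other rows (Fisher exact p = 0.438, with genes counted as independent). Targets without a row, of 40 listed, are unknown. Cdkn1a (0.48), Bbc3 (0.61), Gdf15 (1.45) and Ddit4 (0.98) rose, so arrest through Cdkn1a alone stays open, as does an effect of the genotype on growth, which was not tested. Gdf15 and Ddit4 also belong to the amino-acid response list of the next paragraph, so their rise is not particular to p53.

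A hypothesis is that the stress response extends to the amino-acid branch driven by the transcription factor ATF4, beyond the chaperones of the endoplasmic reticulum. A list of 56 amino-acid response genes outside the unfolded protein response list was written before its test, although the values of Slc7a11 and Slc3a2 had been seen in another list. Of the 37 with a row 94.6% (35 genes) were higher (exact 95% interval 81.8 to 99.3; Fisher exact p = 4.6e-10 against the other rows). The interval and the p-value count genes as independent and do not measure the spread between libraries. Atf5 rose by 1.72, the transaminase Gpt2 by 1.47, the serine-synthesis enzyme Psph by 1.13 and the tRNA synthetases Aars and Nars by 0.65 and 0.55. In the pathway annotation of the deposited table, related terms did not pass: aminoacyl-tRNA biosynthesis had 13 genes higher and 14 lower (adjusted p = 0.916) and biosynthesis of amino acids 15 higher and 22 lower (adjusted p = 0.706). The share of the fixed list is consistent with ATF4 activity on those genes, while over each wider pathway genes went both ways. Other stresses, amino-acid supply included, could also activate ATF4; the data do not tell these apart.

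Alleles that flank the targeted locus, carried over from the strain in which it was made, may add fold changes near Nus1 if the groups differ in them. The Ctrl mice were Nus1fl/fl and carried the targeted locus too. Such alleles would then be in both groups, which argues against this source unless breeding differed. How the groups were bred is not given in the sources used here. Of 20 other rows within 10 Mb of Nus1, 30% (6 genes) had an absolute log2 fold change of at least 0.5, beside 18.1% of 4619 rows elsewhere (Fisher exact p = 0.238; exact 95% interval of the first share 11.9 to 54.3). The 20 rows are too few for this count to decide it. Ddit4 (0.98), Crybg1 (0.79) and Smpdl3a (-0.62) are among the 6, and their changes carry this doubt only if the groups differed in these alleles.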
